A study of Cricetulus griseus with 40 samples.

How the data were processed

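RNA was measured in CHO-S cells, a line of Chinese hamster ovary cells that grows in suspension and is used to make recombinant proteins. The cells were grown in batch culture, in which no nutrients are added after seeding, and were sampled every 12 h from 72 h to 180 h after seeding. Each of the 10 times has 4 libraries, 40 in all, made with a kit for stranded messenger RNA and sequenced as read pairs, per the labels' protocols. The series' design text gives 4 as the number of cultures, but no label says which library came from which culture. The p-values measure the spread between the 4 libraries of a time, part of which may be technical.

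The deposited files hold FPKM (fragments scaled to the length of the transcript and the size of the library) for each NCBI gene ID, 1 file per library. The authors used FastQC, Trimmomatic 0.32, SAMtools 1.0 and Cufflinks 2.2.1, per the submitters' processing notes. The aligner, the genome build, the annotation and the strand setting of the counting are not given in the sources used here. Every file has 27868 lines of values, of which 23 carry no gene ID and hold 0 in every library. The other lines carry 26793 gene IDs, and 634 IDs stand on more than 1 line (1686 lines, up to 76 for 1 ID). The 40 files list their lines in 40 different orders, so lines of the same ID could not be matched between files and their FPKM were summed. The 13 mitochondrially encoded genes are listed at 0 in every library. Since every cell uses them, a 0 in these files can be a failed estimate, and a gene is only said to be listed at 0. Gene symbols came from a reference table of assembly CriGri-PICRH-1.0, used for names only: 23196 IDs matched, and 15217 of these have a symbol that is not a placeholder. No genome sequence was used, so GC content and transcript length were not examined, and reads shared between near-identical genes, such as ribosomal protein genes and their processed copies, could not be told apart.

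FPKM carry no read counts, and the absolute depth of the libraries is unknown. Relative depth was estimated from low values between 0.001 and 0.3 FPKM, which move in steps of the value of 1 fragment. It ran from 0.82 to 1.24, a ratio of 1.512 between the deepest and the shallowest library, with a residual SD of 0.001 on the log2 scale over pairs of libraries. No pair of libraries holds identical values.

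The design had been written for either counts or normalised values, and the branch for normalised values was used. Genes with at least 1 FPKM in at least 4 libraries were kept: 12259 genes, of which 9221 have a symbol, 3038 have a placeholder name and 364 stand on more than 1 line. Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (a mean per time, moderated variances with a trend on mean expression and robust estimation, 30 residual degrees of freedom). A gene passed at a Benjamini-Hochberg adjusted p below 0.05. All adjusted p-values of genes are two-sided and come from limma. Log2 changes are on the log2(FPKM + 1) scale, which understates the change of low genes. The comparisons were the test over all 10 times, 180 h against 72 h, 3 windows of 36 h, the 9 steps of 12 h, midway times (120 and 132 h) against both ends (72, 84, 168 and 180 h), and the change of the third window minus that of the first. A midway gene also had to lie beyond both ends on average, which is not tested by that contrast.

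Before the data were examined, 32 gene lists, the design, most alternatives and the rule for naming genes were fixed. The lists cover DNA replication, mitosis, cholesterol and fatty acid synthesis, fatty acid oxidation, glycolysis, the tricarboxylic acid cycle and nuclear-encoded oxidative phosphorylation. They also cover the ATF4, heat shock, hypoxia, NRF2, p53 and interferon responses, aminoacyl-tRNA synthetases, endoplasmic reticulum chaperones, apoptosis genes for and against, lysosomes, ribosomal proteins, ribosome biogenesis and the proteasome. The rest are 2 lists of N-glycan genes, metallothioneins and zinc transport, immediate early genes, amino acid transporters, glutamine and branched-chain amino acid breakdown, extracellular matrix, host cell proteins that persist in purified products, mitochondrially encoded genes and markers of other cell types. Of these, 30 had the 5 measured genes needed for a test. No mitochondrially encoded gene was measurable, and 2 of 24 markers of other cell types found in the files were measured. Each list was tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 30 lists, with camera at an estimated correlation and with fry beside it. Camera compares a list with all other genes. Fry's directional p tests whether a list's genes move, on balance, 1 way, and its mixed p whether they change in either direction, without comparing them with other genes. Counts of list members past the test are given over all genes and, where they differ, adjusted over the list alone.

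The genes named for 180 h against 72 h are the 12 largest rises and 12 largest falls among genes past the test, with all 4 libraries of 1 time above all 4 of the other, at least 5 FPKM at the higher time and a proper symbol. Each window and the midway contrast gave 6 each way by the same rule, without the condition on overlap for midway, and the step with the most changed genes gave 5 each way. Each list gave up to 3 members in the direction more of its members took and 1 the other way. Gapdh, Actb, Asns, Ldha, Hspa5, Mki67, Pcna, Ddit3, Cdkn1a and Glul were fixed by name. Some genes that the rule names are not reported here. Genes named outside this rule are marked as chosen after their values were seen.

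The procedure was tested on simulated data with the spread of the real 12259 genes. For 180 h against 72 h it recovered 40% of 100 genes changed by 0.5 on the log2 scale and 86% of 100 genes changed by 1 on that scale, and 9 unchanged genes passed (6.7% of calls). No gene passed in a simulated window with no change. The simulated noise was independent between genes and lacked the axis that real libraries of a time shared. These error rates therefore need not hold for the real data. The alternatives were another pseudocount, other filters on low values, the replicate number as a block, fits of only the compared libraries, each library left out in turn, a minimum fold change, a straight line in time, and pairs of times at both ends. Median-ratio scaling, genes on more than 1 line left out, array weights, 2 covariates for an axis shared by libraries within times, the removal of the 2 libraries farthest out on it, and a test of midway against each end separately were chosen after seeing the data. One covariate, the control-gene axis, is the first principal component of 2613 genes with an adjusted p above 0.5 over all times, and the other that of all genes' deviations from their time means. Alternatives were run for all lists at 180 h against 72 h and, in the windows, only for lists past the test, a restriction made after a wider set had been computed. Alternatives that need counts were not run. Tables were handled with the R package data.table, version 1.17.8, and with pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.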

Results

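The series followed the transcriptome of CHO-S cells, a suspension line of Chinese hamster ovary cells, through a batch culture from 72 h to 180 h after seeding, with 4 libraries at each of 10 times. The FPKM of a library summed to between 463992 and 575241 (median 531047), and between 10904 and 11537 genes reached 1 FPKM. Relative depth lay between 0.82 and 1.24, and the absolute depth is unknown. Within a time, libraries correlated across genes with r between 0.906 and 0.990 (median 0.977), and libraries of 72 h and 180 h with r between 0.887 and 0.943 (median 0.927).

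Time made up much of the main axis of the data. The first principal component held 50.6% of the variance, and 62.8% of it lay between times. Replicate numbers, which do not pair the libraries, held 3.13% of it. Times overlapped on this component: replicate 4 of 180 h scored -2.09 and replicate 3 of 96 h 7.40. The second component held 16.6% of the variance. Libraries of the same time also differed along a shared axis, which held 52.4% of the variance within times, against 4.2% for the next. Along this axis, per SD of its score, the median log2 value of host cell proteins moved by 0.15, of ATF4 targets by 0.15, of cytosolic ribosomal proteins by 0.14, of immediate early genes by 0.13 and of glycolysis genes by 0.12. The medians of the extracellular matrix and lysosome lists moved by 0.08 each and that of mitotic genes by -0.11. Single genes moved more than these medians, for example Gapdh, fixed by name, by 0.56. The lowest score of a time belonged to replicate 4 at 84, 108, 132, 156 and 180 h, to replicate 1 at 96, 120, 144 and 168 h and to replicate 2 at 72 h. The libraries farthest out were replicate 4 of 84 h and replicate 1 of 96 h. The median SD of a gene was 0.16 on the log2 scale at 72 h, 0.25 at 84 h, 0.26 at 96 h and 0.17 at 180 h.

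**Figure D1:**
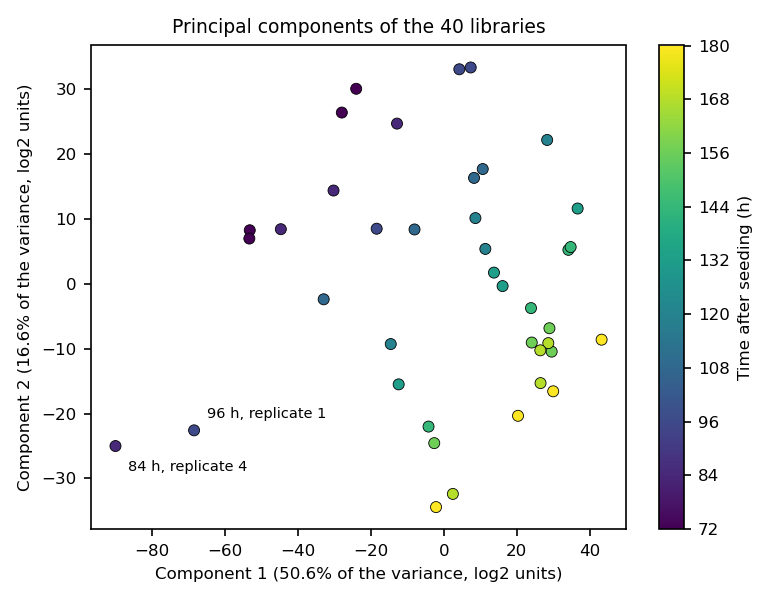
Each point is 1 of the 40 libraries, placed by its scores on the first component (x axis, 50.6% of the variance) and the second (y axis, 16.6%), in log2 units, and coloured by hours after seeding. Early libraries lie mostly to the left, with overlap between times, and replicate 4 of 84 h and replicate 1 of 96 h lie apart from the rest.

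Between 72 h and 180 h all 40 measured genes of G2 phase and mitosis fell, and 33 of 42 genes of lysosomes and autophagy rose. Spp1, which encodes the secreted phosphoprotein osteopontin, rose from 75.9 ± 22.4 to 4656 ± 421 FPKM (mean ± SD, n = 4 per time; log2 change 5.98 ± 0.20 SE, adjusted p = 1.44e-21). Mki67, a marker of proliferating cells, fell from 73.9 ± 8.14 to 6.85 ± 1.72 FPKM (-3.28 ± 0.18, adjusted p = 8.24e-17), and Top2a, the topoisomerase that separates chromosomes, from 247 ± 20.0 to 26.4 ± 5.91 FPKM (-3.20 ± 0.16). Fth1, the ferritin heavy chain that stores iron, rose from 6485 ± 845 to 31349 ± 1745 FPKM (2.28 ± 0.10) and came to 5.89 ± 0.41% of all FPKM at 180 h, against 1.29 ± 0.16% at 72 h.

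The other genes with the largest rises included the matrix metalloproteinases Mmp9 (log2 change 3.95 ± 0.47, adjusted p = 1.94e-08) and Mmp12 (3.55 ± 0.18), the secreted chaperone Clu (3.82 ± 0.22) and the natriuretic peptide precursor Nppb (3.79 ± 0.44). Serpinf1 (3.63 ± 0.12), the lipid transfer protein gene Pltp (3.51 ± 0.33) and Aebp1 (3.51 ± 0.27) also encode proteins found outside cells. The lysosomal sialidase Neu1 rose by 3.72 ± 0.72 (adjusted p = 5.79e-05), from 11.2 ± 6.49 to 170 ± 103 FPKM, with wide spread at both times. Its lysosomal partner Ctsa rose from 420 ± 70.8 to 5112 ± 788 FPKM (3.60 ± 0.28), the lysosomal membrane protein gene Cd68 from 11.6 ± 1.64 to 150 ± 8.85 FPKM (3.60 ± 0.13) and progranulin, Grn, from 214 ± 25.8 to 2135 ± 233 FPKM (3.31 ± 0.25). Of the 12 largest rises, Neu1 moved most along the axis within times (0.91 per SD of its score), then Mmp9 (0.60), Nppb (0.55) and Pltp (0.41). Spp1 (-0.13) and Mmp12 (-0.14) moved the other way, and the rest by 0.02 to 0.33. The other large falls were those of Pclaf (-3.13 ± 0.16), Ect2 (-2.95 ± 0.12), Kif15 (-2.95 ± 0.13), Ccna2 (-2.92 ± 0.16), Anln (-2.92 ± 0.13), Hmmr (-2.89 ± 0.16), Nusap1 (-2.88 ± 0.15), Ccnb1 (-2.88 ± 0.12), Dlgap5 (-2.86 ± 0.14) and Prr11 (-2.84 ± 0.13).

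**Figure D2:**
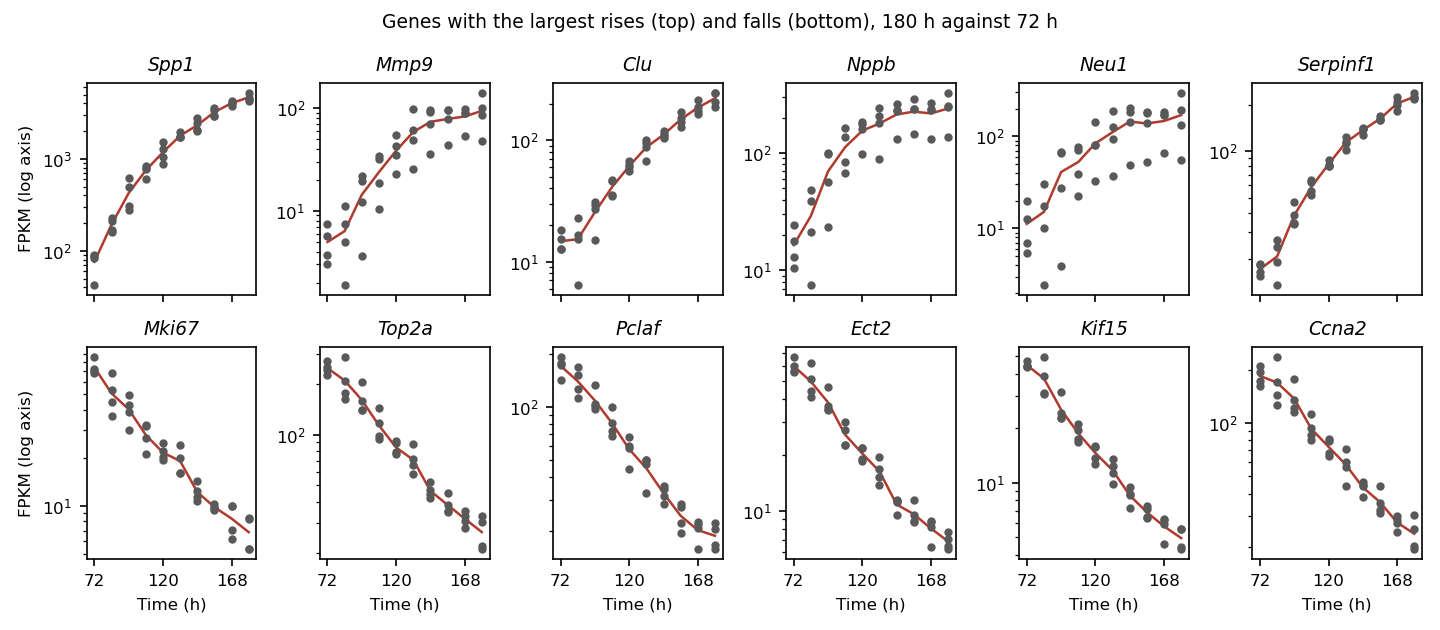
FPKM (y axis, log scale) against hours after seeding (x axis) for the 6 largest rises (top) and 6 largest falls (bottom) between 72 h and 180 h; points are libraries (4 per time) and lines join the means. Spp1 climbs from 75.9 to 4656 FPKM, while Mki67 drops from 73.9 to 6.85 FPKM.

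Genes of cell division fell as groups. All 40 measured genes of G2 phase and mitosis fell (median log2 change -2.40, camera adjusted p = 8.37e-37; adjusted p = 0.00157 with an estimated correlation). Of 41 genes of DNA replication and S phase 36 fell and 0 rose (median -1.58, adjusted p = 1.24e-19; adjusted p = 0.00127 with an estimated correlation). Examples were the ribonucleotide reductase subunit Rrm2 (-2.44 ± 0.13), the helicase component Gins1 (-2.28 ± 0.19), the origin licensing factor Cdc6 (-2.27 ± 0.13) and the polymerase clamp Pcna (-1.45 ± 0.10).

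Several groups of biosynthesis and metabolism were also lower at 180 h. In cholesterol synthesis 12 of 22 genes fell and 0 rose (median -0.61, adjusted p = 7.78e-04; adjusted p = 0.0813 with an estimated correlation), among them the synthase Hmgcs1 (-1.31 ± 0.11), the sterol carrier Stard4 (-1.30 ± 0.13) and Hsd17b7 (-1.26 ± 0.07). The tricarboxylic acid cycle had 18 of 23 genes lower (median -0.43, adjusted p = 2.98e-04; adjusted p = 0.214 with an estimated correlation), with fumarase Fh at -0.90 ± 0.08 and Suclg2 at -0.88 ± 0.09. Cytosolic aminoacyl-tRNA synthetases, which charge tRNAs for translation, had 15 of 20 genes lower (median -0.58, adjusted p = 4.96e-05; adjusted p = 0.0671 with an estimated correlation), led by Iars1 (-1.27 ± 0.10), Gars1 (-1.20 ± 0.09) and Rars1 (-1.08 ± 0.14). Of 44 ribosome biogenesis genes 26 fell and 1 rose (median -0.41, adjusted p = 0.00486; adjusted p = 0.0943 with an estimated correlation). The pseudouridine synthase Dkc1 fell by 0.93 on the log2 scale, and Nop10 was the riser (0.51 ± 0.10). Cytosolic ribosomal proteins had 35 of 72 genes lower and 0 higher (median -0.39, adjusted p = 0.00499; adjusted p = 0.568 with an estimated correlation), for example Rps25 (-1.05 ± 0.13) and Rps4x (-0.97 ± 0.13). This list was among those that moved most along the axis within times.

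The groups that rose were led by lysosomes and the extracellular matrix. In the lysosome and autophagy list 33 of 42 genes rose and 2 fell (34 and 2 adjusted over the list alone; median 0.98, adjusted p = 1.01e-18; adjusted p = 0.00157 with an estimated correlation). The protease Ctsb rose from 358 ± 22.3 to 3283 ± 155 FPKM (3.19 ± 0.12), whereas the autophagy initiator Becn1 fell by 0.37 on the log2 scale, a call lost with median-ratio scaling. Extracellular matrix and adhesion had 18 of 26 genes higher and 1 lower (20 and 1 adjusted over the list alone; median 1.15, adjusted p = 1.65e-10; adjusted p = 0.0642 with an estimated correlation). Its examples were stromelysin Mmp3 (2.90 ± 0.13) and, the other way, thrombospondin Thbs1 (-1.05 ± 0.11). Of 27 host cell proteins known to persist in purified products 19 rose and 1 fell (median 0.87, adjusted p = 2.63e-10; adjusted p = 0.0405 with an estimated correlation). Clu and Ctsb were among the former, and Sod1 fell by 0.29 on the log2 scale. Ctsb is also in the lysosome list, so the host cell protein and lysosome lists are not separate evidence.

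The other lists that camera called upward had members past the test in both directions. Interferon-stimulated genes had 11 of 21 members higher and 3 lower (median 0.47, adjusted p = 1.05e-04; adjusted p = 0.0462 with an estimated correlation), with the MHC light chain B2m at 1.91 ± 0.08, Irf9 at 1.34 ± 0.12 and the chemokine Cxcl10 at -1.17 ± 0.13. Immediate early genes, which respond to growth factors and stress, had 14 of 19 higher and 1 lower (median 0.54, adjusted p = 4.02e-05; adjusted p = 0.214 with an estimated correlation). Ccn2 (1.31 ± 0.08) and Atf3 (1.02 ± 0.16) rose and Egr1 fell (from 10.05 ± 2.06 to 4.47 ± 0.66 FPKM). Endoplasmic reticulum chaperones and unfolded protein response genes had 13 of 27 higher and 1 lower (13 and 2 adjusted over the list alone; median 0.27, adjusted p = 0.00133; adjusted p = 0.196 with an estimated correlation), including Pdia6 (0.74 ± 0.20), calreticulin, Calr (0.72 ± 0.11), and Hspa5 (0.32 ± 0.10), against the oxidase Ero1a (-0.59 ± 0.12). Golgi N-glycan processing had 8 of 36 higher and 6 lower (median 0.18, adjusted p = 0.0369; adjusted p = 0.0943 with an estimated correlation), with the branching enzyme Mgat5 at 0.93 ± 0.08 and Uap1, which makes a nucleotide sugar, at -0.84 ± 0.12. Pro-apoptotic genes had 4 of 18 higher and 3 lower (median 0.25, adjusted p = 0.0471; adjusted p = 0.338 with an estimated correlation). The BH3-only genes Bmf (1.67 ± 0.19), Bcl2l11 (1.58 ± 0.10) and Bid (1.06 ± 0.06) rose and Casp8 fell (-1.12 ± 0.13). This list's call was lost with a filter of 5 FPKM (adjusted p = 0.051) and with the control-gene axis as a covariate (adjusted p = 0.0523).

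**Figure D3:**
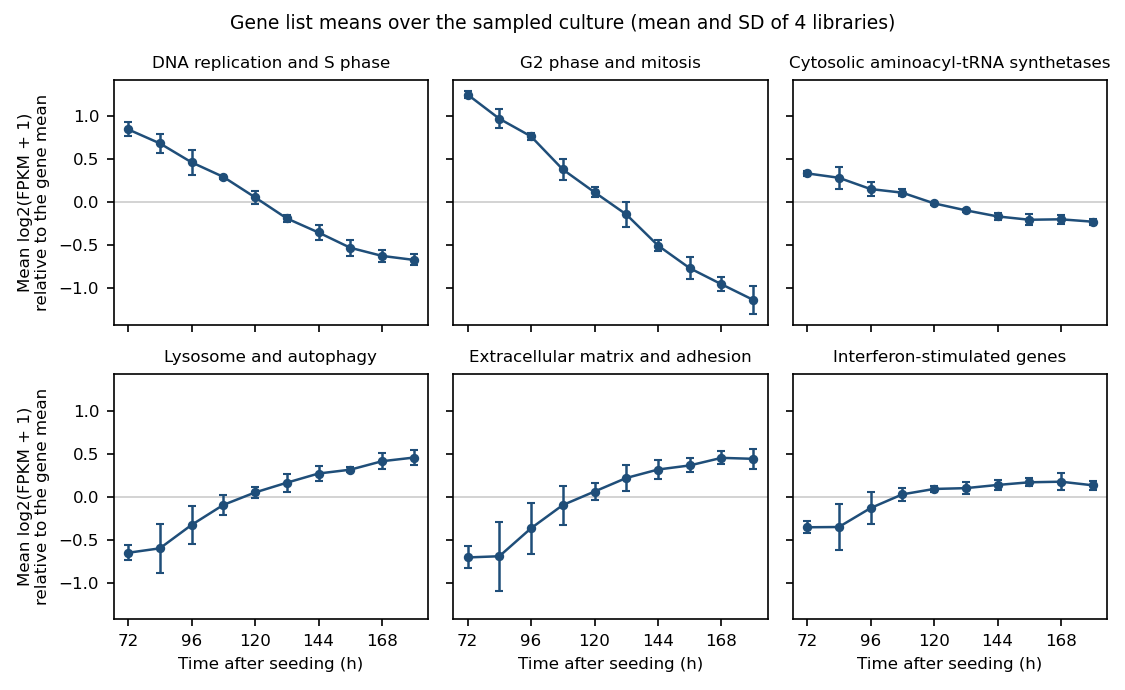
Mean log2(FPKM + 1) of 6 gene lists relative to each gene's own mean (y axis) against hours after seeding (x axis); points and bars are the mean and SD of 4 libraries. The lists of DNA replication, mitosis and tRNA synthetases decline and the lists of lysosome, extracellular matrix and interferon-stimulated genes rise. Bars are widest at 84 and 96 h, except for the mitosis list.

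Other lists were mixed or did not pass camera. Amino acid starvation genes driven by ATF4 had 4 of 26 higher and 12 lower (adjusted p = 0.0715). The serine synthesis enzyme Psat1 (-2.11 ± 0.11), Stc2 (-1.41 ± 0.11) and asparagine synthetase, Asns (-1.21 ± 0.07), fell, while Nupr1 (1.05 ± 0.19) and the stress factor Ddit3 (0.76 ± 0.19, adjusted p = 0.0016) rose. This list passed with median-ratio scaling (adjusted p = 0.031), with a filter of 5 FPKM (adjusted p = 0.0256) and with the control-gene axis as a covariate (adjusted p = 0.0187). NRF2 targets had 5 of 20 higher and 10 lower (adjusted p = 0.361): the glutathione synthesis genes Gclm (-1.31 ± 0.12) and Gclc (-0.85 ± 0.12) and thioredoxin, Txn (-0.78 ± 0.08), fell against the rise of Fth1. Glycolysis had 4 of 18 higher and 3 lower (adjusted p = 0.202), with Pfkfb3 at 0.73 ± 0.06 and the lactate transporter Slc16a1 at -0.77 ± 0.11. Hypoxia genes had 7 of 20 higher and 5 lower (adjusted p = 0.18; adjusted p = 0.0236 with a filter of 5 FPKM), with Bhlhe40 at 1.78 ± 0.11 and adrenomedullin, Adm, at -1.71 ± 0.20.

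Fatty acid synthesis had 1 of 13 genes higher and 6 lower (1 and 8 adjusted over the list alone; adjusted p = 0.173), including Acss2 (-1.42 ± 0.09) and the citrate lyase Acly (-1.12 ± 0.07). Fatty acid oxidation had 3 of 21 higher and 7 lower (adjusted p = 0.80), and glutamine and branched-chain amino acid breakdown 3 of 26 higher and 14 lower (adjusted p = 0.237), with glutamine synthetase, Glul, among the rises (0.47 ± 0.09). The proteasome had 16 of 29 lower and 0 higher (adjusted p = 0.214), and heat shock genes 8 of 15 lower and 0 higher (adjusted p = 0.18), with the chaperonin Hspd1 at 316 ± 22.6 and then 158 ± 17.4 FPKM. Oxidative phosphorylation had 1 of 19 higher and 7 lower (adjusted p = 0.666), and its median of 0.01 differed in sign from its mean of -0.07 and from camera's direction. Amino acid transporters had 3 of 18 higher and 4 lower (adjusted p = 0.959; median -0.13, mean 0.004), with the creatine transporter Slc6a8 at 1.90 ± 0.25 and the glutamate transporter Slc1a3 at -1.02 ± 0.10. N-glycan precursor genes had 8 of 31 higher and 9 lower (adjusted p = 0.233), p53 targets 6 of 20 higher and 3 lower (4 and 1 adjusted over the list alone; adjusted p = 0.158), and anti-apoptotic genes 2 of 12 higher and 3 lower (adjusted p = 0.242), with Cflar at 1.36 ± 0.10. Metallothionein and zinc transport genes had 2 of 5 higher and 1 lower (2 and 2 adjusted over the list alone; adjusted p = 0.476). Of the genes fixed by name, Gapdh (0.49 ± 0.44, adjusted p = 0.376), Actb (0.57 ± 0.28, adjusted p = 0.0957), Ldha (0.10 ± 0.11, adjusted p = 0.445) and Cdkn1a (0.10 ± 0.28, adjusted p = 0.786) did not pass.

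In total, 6118 of 12259 genes (49.9%) differed among the 10 times, and at 180 h against 72 h 1938 were higher and 4101 lower, of which 554 and 621 by at least 2-fold. With array weights 3383 were higher and 5025 lower, and both axis covariates gave similar counts (3140 and 5009, 3372 and 5019). Camera called 15 of 30 lists, 8 upward and 7 downward, of which the lists of mitosis, DNA replication, lysosome, interferon-stimulated genes and host cell proteins held with an estimated correlation. With the control-gene axis as a covariate 0 lists held with an estimated correlation, and with median-ratio scaling 10 did. Fry's directional test passed for 26 lists and its mixed test for 29. The median change of all genes was -0.10 on the log2 scale and 0.01 with median-ratio scaling, which gave 2691 genes higher and 2994 lower. Small changes hold only relative to that shift.

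The early part of the culture, from 72 h to 108 h, held the largest rises of the 3 windows. Spp1 rose by 3.34 ± 0.20, Nppb by 2.68 ± 0.44, the small GTPase gene Gem by 2.62 ± 0.12 (from 7.24 ± 1.87 to 48.8 ± 5.81 FPKM, n = 4, adjusted p = 1.53e-16) and the alarmin Il33 by 2.57 ± 0.16 (from 58.0 ± 14.3 to 344 ± 37.2 FPKM). Neu1 (2.13 ± 0.72, adjusted p = 0.0342) and Mmp9 (1.98 ± 0.47) followed. The largest falls were Mki67 (-1.39 ± 0.18), the water channel Aqp1 (-1.29 ± 0.11), Kif15 (-1.22 ± 0.13), Hmmr (-1.21 ± 0.16), Ect2 (-1.20 ± 0.12) and Cenpf (-1.16 ± 0.16). Mitotic genes fell in 39 of 40 (40 adjusted over the list alone; median -0.89) and S phase genes in 27 of 41 (28 adjusted over the list alone), while 25 of 42 lysosomal genes rose (30 adjusted over the list alone; median 0.54). Matrix genes rose in 13 of 26 (14 adjusted over the list alone; adjusted p = 0.0841 with an estimated correlation) and immediate early genes in 7 of 19 (8 adjusted over the list alone; adjusted p = 0.38 with an estimated correlation). Altogether 914 genes rose and 1379 fell. The excess of falls turned with array weights (3434 and 3358), with the within-time axis as a covariate (3092 and 2841) and with a minimum fold of 2 (125 and 47). Without the 2 libraries farthest out 1444 rose and 1855 fell. Camera called 11 lists, of which mitosis, S phase, lysosome and interferon-stimulated genes held with an estimated correlation.

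From 108 h to 144 h, falling genes outnumbered rising ones, and the proteasome was among the groups with members lower. The proteasome, which degrades tagged proteins, had 13 of 29 genes lower and 0 higher (20 and 0 adjusted over the list alone; median -0.31, adjusted p = 1.88e-05; adjusted p = 0.105 with an estimated correlation), for example Psma4 (-0.54 ± 0.15) and Psma5 (-0.49 ± 0.12). Ribosome biogenesis had 15 of 44 lower (21 adjusted over the list alone; adjusted p = 5.17e-05 and 0.0259 with an estimated correlation), with Dkc1 at -0.63 ± 0.12 and Nop56 at -0.49 ± 0.06. The largest rises were Mmp9 (1.63 ± 0.47, adjusted p = 0.017), Spp1 (1.63 ± 0.20), the matrix protein periostin, Postn (1.51 ± 0.14), Clu (1.42 ± 0.22), Pltp (1.42 ± 0.33) and Aebp1 (1.33 ± 0.27). The largest falls were the kinetochore gene Nuf2 (-1.38 ± 0.17), Pclaf (-1.28 ± 0.16), the mitotic kinase Pbk (-1.26 ± 0.15), Top2a (-1.25 ± 0.16), Ccnb2 (-1.19 ± 0.10) and Mnd1 (-1.19 ± 0.18). Mitotic genes fell again in 39 of 40 (40 adjusted over the list alone), and lysosomal genes rose in 11 of 42 (15 adjusted over the list alone). In all, 371 genes rose and 1553 fell, against 601 and 759 with median-ratio scaling. Array weights and both axis covariates gave more genes each way, as given with the processing. Camera called 17 lists, and mitosis, S phase, lysosome and ribosome biogenesis held with an estimated correlation. Without replicate 4 of 108 h the counts were 207 and 804.

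The last window, from 144 h to 180 h, held fewer changes, and mitotic genes went on falling. Of 40 mitotic genes 27 fell (39 adjusted over the list alone; median -0.61, adjusted p = 4.26e-05 with an estimated correlation), among them the mitotic kinase Aurkb (-0.93 ± 0.12), the anaphase activator Cdc20 (-0.94 ± 0.21), the centromeric histone Cenpa (-0.92 ± 0.12), Knstrn (-0.89 ± 0.12) and Tacc3 (-0.89 ± 0.10). The transcription factor gene Egr1 fell by 1.07 on the log2 scale. Mmp12 (1.33 ± 0.18), the hydroxybutyrate receptor Hcar2 (1.05 ± 0.14), Spp1 (1.01 ± 0.20), Clu (0.98 ± 0.22), the adhesion molecule Vcam1 (0.94 ± 0.12) and Postn (0.92 ± 0.14) were the largest rises. No cholesterol synthesis gene passed over all genes, but 7 of 22 were lower adjusted over the list alone, and the list, with a median of -0.27, passed camera (adjusted p = 6.79e-08; adjusted p = 0.00512 with an estimated correlation). Altogether 58 genes rose and 112 fell by limma, and 988 had an unadjusted p below 0.05. With median-ratio scaling the counts were 87 and 85. With only the compared libraries 32 rose and 44 fell, and without replicate 1 of 180 h 67 fell. More genes passed each way with array weights, with either axis covariate and without the 2 libraries farthest out, as given with the processing. Camera called 12 lists, and 5 held with an estimated correlation: mitosis, S phase, cholesterol synthesis, lysosome and endoplasmic reticulum chaperones, the last with 0 members past the test over all genes (1 higher adjusted over the list alone) and a median of 0.09.

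The change of the first window was then compared with that of the third. By the test of the difference on the log2 scale, the change of Il33 (-2.76), Gem (-2.55), Nppb (-2.53) and Spp1 (-2.33) was lower in the third window than in the first, and that of Aqp1 was higher (0.92, adjusted p = 7.01e-04). In all, 401 genes passed, and 252 without replicate 1 of 108 h. More passed with array weights, with either axis covariate and without the 2 libraries farthest out, as given with the processing. Chance stays open: 5 of 100 splits of the same libraries gave as many. Those splits mix different times and can line up with the change over time, so they do not decide it. Camera called 13 lists, none of which held with an estimated correlation. Across genes, which are not independent replicates, the changes of both windows, which share no library, correlated with r = 0.136 and rho = 0.046. Of the 58 genes higher in the third window 49 were also higher in the first (4.3 for independent lists), and of the 112 lower 95 were also lower (12.6 for independent lists).

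Of the 12 h steps, the first had the most genes past the test, but with array weights or the within-time axis as a covariate the second had more (5598 against 1816 and 4595 against 2516). Between 72 h and 84 h, Il33 rose from 58.0 ± 14.3 to 189 ± 13.0 FPKM (1.72 ± 0.16, n = 4, adjusted p = 3.08e-08), and Gem (1.45 ± 0.12), Spp1 (1.38 ± 0.20), the cold-inducible RNA-binding protein gene Rbm3 (0.89 ± 0.11) and the growth factor epiregulin, Ereg (0.88 ± 0.13), rose too. Aqp1 fell from 127 ± 7.90 to 55.6 ± 3.15 FPKM (-1.18 ± 0.11), followed by Syne2 (-0.86 ± 0.22, adjusted p = 0.0393), the amino acid transporter Slc1a4 (-0.54 ± 0.08) and Ccdc163 (-0.51 ± 0.10). In that step 91 genes rose and 70 fell, and from 84 h to 96 h 17 rose and 35 fell. The 161 genes of the first step were 62 and 53 without replicates 3 and 4 of 72 h, 83 and 102 without replicates 2 and 3 of 84 h, and 2 with only the compared libraries. The latter count was 2218 without replicate 1 of 96 h, 1 without replicate 3 of 84 h and 0 with only the compared libraries. For that step 7 of 35 splits of the libraries gave as many genes.

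In later steps few genes passed, and they are named here after their values were seen. Some counts were far higher once the shared axis was modelled: the steps from 96, 108 and 132 h gave 618, 434 and 102 genes with the control-gene axis as a covariate, against 7, 2 and 0. They gave 1246, 1521 and 218 with the within-time axis, which narrows the spread by construction, and 479, 158 and 365 with array weights. The control-gene axis also comes from these same libraries, so its counts are not independent of their spread. From 96 h to 108 h, Gem (0.65 ± 0.12), Serpinf1 (0.60 ± 0.12), Gldc (0.54 ± 0.11) and Spry2 (0.38 ± 0.07) rose and the spindle genes Kif2c (-0.48 ± 0.10) and Spag5 (-0.42 ± 0.08) and 1 gene without a symbol fell. Egr1 rose from 108 h to 120 h (1.00 ± 0.18, adjusted p = 0.0278), when Cdca7 fell (-0.39 ± 0.07), then fell to 132 h (-1.51 ± 0.18, adjusted p = 1.71e-05) and again from 168 h to 180 h (-1.09 ± 0.18, adjusted p = 0.0128). By limma 0 genes passed from 132 h to 144 h, from 144 h to 156 h and from 156 h to 168 h, where 454, 205 and 289 genes had an unadjusted p below 0.05. With array weights genes passed in the steps from 144 and 156 h too, and from 144 h also with either axis covariate. With 1 library left out, the 7 genes from 96 h to 108 h became 0 to 35 and the 2 from 108 h to 120 h became 0 or 1. The 1 from 168 h to 180 h became 0 without any 1 of 6 libraries and with only the compared libraries. For that step 3 of 35 splits gave as many.

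**Figure D4:**
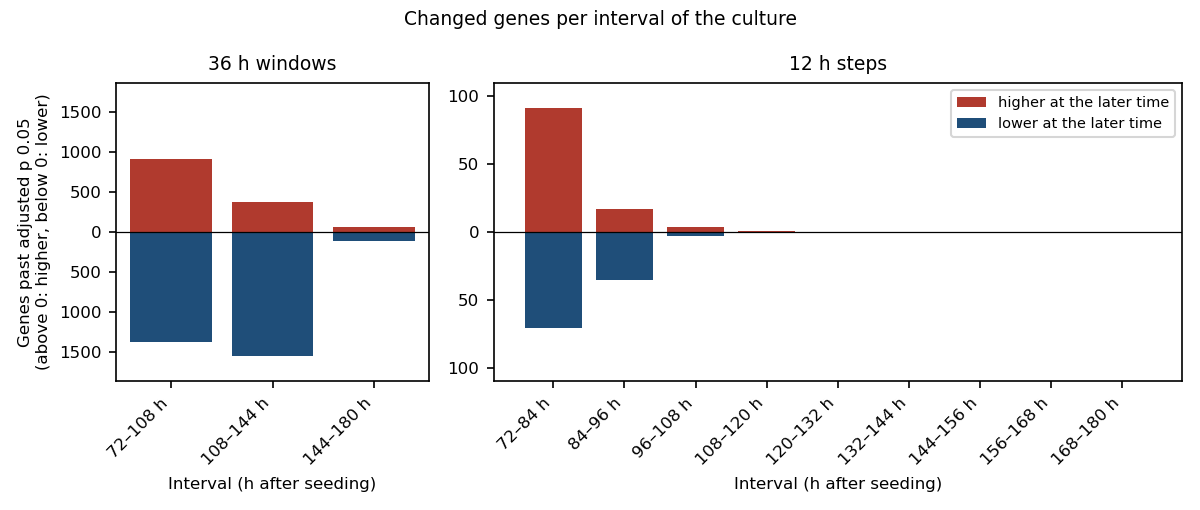
Number of genes past an adjusted p of 0.05 (y axis; above 0 higher and below 0 lower at the later time) for the 3 windows of 36 h (left) and the 9 steps of 12 h (right, another scale). The windows have 914, 371 and 58 genes higher and 1379, 1553 and 112 lower, so the lower bar is longest in the middle window.

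Midway through the sampled period, at 120 and 132 h, 258 genes were higher and 168 lower than the pooled mean of the early end (72 and 84 h) and the late end (168 and 180 h). With median-ratio scaling the balance turned, to 203 higher and 289 lower. A gene that had reached its level by 120 h and kept it also passes this contrast. Each end was therefore tested on its own, and 46 of the 258 and 14 of the 168 passed against both. Among the genes with the largest pooled differences, the cystine transporter Slc7a11 was lower midway than at the early end (-0.48 ± 0.07) and the late end (-0.31 ± 0.07, adjusted p = 0.00203). Sema3c was also lower than at both (-0.31 ± 0.09 and -0.36 ± 0.09, adjusted p = 0.00303 and 0.00218). Il33 had a mean of 124 FPKM at the early end, 375 ± 41.5 midway and 347 ± 42.4 at the late end (n = 8 each). It was higher midway than at the early end (1.84 ± 0.12, adjusted p = 1.26e-14), and its difference of 0.11 ± 0.12 from the late end did not pass (adjusted p = 0.602).

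The polyamine oxidase Smox (1.86 ± 0.28), Smim29 (1.95 ± 0.35), the galectin Lgals1 (1.91 ± 0.40), Arhgap22 (1.64 ± 0.30) and Trim54 (1.68 ± 0.28) were likewise higher midway than at the early end. Their differences from the late end, 0.09 to 0.25, did not pass (adjusted p = 0.722 to 0.89). These 5 genes moved by 0.49 to 0.71 per SD along the axis within times. The control-gene axis comes from part of the same genes and ordered the libraries of each time as the axis within times did. Unlike that axis, it keeps differences between times: the mean of its score was 0.39 ± 0.90 at 120 h and 0.27 ± 0.92 at 132 h (SD, n = 4). At 72, 84, 168 and 180 h it was -0.34 ± 0.86, -0.82 ± 1.58, -0.03 ± 0.67 and -0.06 ± 0.84, with wide spread between libraries. With this score as a covariate their pooled differences of 0.88 to 1.10 still passed but were 0.53 to 0.68. Gclc (-0.78 ± 0.09), needed like Slc7a11 to make glutathione, Fbxl17 (-0.52 ± 0.09), the deacetylase Sirt1 (-0.63 ± 0.10) and Ppp1r2 (-0.59 ± 0.09) were lower midway than at the early end. Their differences from the late end, -0.19 to -0.02, did not pass (adjusted p = 0.18 to 0.933). The pooled call of Lgals1 was lost without any 1 of 13 libraries, that of Arhgap22 without any of 6, of Smim29 of 3, and of Trim54 and Sirt1 of 2 each. With each library left out in turn the pooled counts ranged from 133 to 509 higher and from 67 to 341 lower.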

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

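The tests of the axis within times, of scaling and of that axis as a source of the rising genes were chosen only after the results were seen, apart from the test of libraries matched across times, which was written before its result, after the order of the scores had been noticed. The bound for blood cell markers was also written after the results were seen, and its restriction to markers not listed at 0 after their values were seen. The comparisons of other splits and the test of the windows' difference were set beforehand.

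In 11 of 258 groups of 4 libraries (4.26%; chance gives about 1 in 20) 1 library lay far from the other 3. At 72 h, Spp1 was 42.49 FPKM in replicate 4 (others 83.8 to 89.9), Slc7a11 28.54 FPKM in the same library, Kif15 46.98 and Glul 14.86 FPKM in replicate 2, and Ddit3 75.93 FPKM in replicate 3. Replicate 1 of 120 h had 26.71 FPKM of Gclc, and replicate 1 of 168 h had 54.98 FPKM of Fbxl17 and 21.70 FPKM of Sema3c. Replicate 4 of 180 h had 1.537 FPKM of Cdkn1a and a relative depth of 0.82 (others 1.007 to 1.014), and replicate 4 of 132 h had a total of 507566 FPKM (others 552311 to 561076).

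The change of the third window minus that of the first passed for 7 named genes: Il33 (-2.764 on the log2 scale), Gem (-2.546), Nppb (-2.530), Spp1 (-2.325), Egr1 (-1.228), Aqp1 (0.918) and Ect2 (0.610). By camera it passed for 13 lists, and no adjusted p passed with an estimated correlation. Medians were above 0, a smaller fall or a later rise, for S phase (0.236, adjusted p = 1.05e-06; 0.149 with an estimated correlation), mitosis (0.292; 0.411), tRNA synthetases (0.255; 0.149), NRF2 targets (0.211; 0.149) and ATF4 targets (0.074; 0.590). They were below 0 for immediate early genes (-0.473; 0.428), extracellular matrix (-0.470; 0.411), interferon-stimulated genes (-0.327; 0.149), ribosomal proteins (-0.317; 0.616), lysosome (-0.315; 0.193), host cell proteins (-0.315; 0.428), oxidative phosphorylation (-0.308; 0.547) and pro-apoptotic genes (-0.224; 0.411). Of 100 splits of the same libraries 5 gave as many genes as the real 401, and the highest other split gave 6418. These splits mix libraries of different times and can line up with the change over time. They therefore do not decide on chance, which stays open for this difference.

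Libraries of a time shared an axis with 52.4% of the variance within times. Its score went with the number of genes at 1 FPKM or more (r = 0.868, rho = 0.81, each with permutation p = 1e-05, the smallest possible) and with total FPKM (r = 0.72, rho = 0.738, permutation p = 5e-05 and 1e-05), and without the 2 libraries farthest out r was 0.803 and 0.626. Both measures come from the same FPKM as the score, whose sign was set so that it rose with total FPKM. These relations therefore describe the axis and are no outside evidence on its source. Of the squared gene loadings 17.1% lay along the change from 72 h to 180 h, below the bound for cultures ahead or behind in time. This argues against a lag along that whole change. A lag along the change local to a time was not tested and stays open. Depth also stays open (r = 0.193, interval -0.180 to 0.517, rho = 0.161, permutation p = 0.31 and 0.385). Adjusted over the 3 relations, the permutation p of the Pearson correlations were 3e-05, 7.5e-05 and 0.31. Replicate numbers as labelled held 7.88% of the score's variance, and numbers reversed at every other time, an order read off these same scores, held 82.6%, which describes the scores and is no test. As a hypothesis, the libraries may follow cultures numbered in alternating order, or a position in runs of 8 libraries in handling. These cannot be told apart: with the axis removed, libraries matched by the reversed order had a mean correlation of -0.0221 (random numberings -0.0126 to 0.014), below the bound set for a culture beforehand, but removing the axis pushes matched libraries apart by construction, and with both times left out of its estimate, which pulls them together, the mean was 0.0441 (highest random 0.0275).

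More genes were lower than higher at 180 h, 67.9% of those that changed. With median-ratio scaling the share was 52.7%, but this scaling brings the median change near 0 by construction and so moves the share toward balance whatever the source. Fth1 alone went from 1.29 to 5.89% of all FPKM and the top 10 genes from 6.39 to 13.2%. Scaling between libraries and lower mRNA of many genes cannot be told apart from these values, and no biological explanation was tested.

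Cd68, Spp1, Grn, Mmp12 and lysosomal genes, which macrophages also express, rose together. Of 15 myeloid markers fixed before this test, 13 had a gene ID in the files. Of these 13, 7 were listed at 0 in all 4 libraries of 180 h, which can be failed estimates and decides nothing. The median of the other 6 was 0.144 FPKM: Csf1r was at 0.0813 FPKM, Cd14 at 0.124, Itgam at 0.0147, Fcer1g at 0.661 and Cd53 at 5.69 ± 0.755, and Aif1 was listed at 0 in 3 of the 4 libraries. Of these 6 markers 3 were at 2 times their 72 h mean or more, but all except Cd53 had means below 1 FPKM, which argues against blood cells as the source of the rise. Of the squared changes of the 46 measured genes of this pattern 21.4% (bootstrap interval over genes 3.12 to 48.0) lay along their loadings on the axis within times, which argues against that axis as the whole source. Culture age, RNA quality and dying cells stay open and were not tested.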

How the results depend on the processing

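Median-ratio scaling, genes on more than 1 line left out, the removal of the 2 libraries farthest out, array weights, both axis covariates and the test of midway against each end were chosen after seeing the data; the others were set beforehand. Alternatives that need counts (median-of-ratios factors in a count test, totals, count filters, count tests and voom) were not run, since the files hold FPKM. Of 279 values of named genes 275 passed, and 43 lost their call without some 1 library. Calls of named genes were lost for 12 with median-ratio scaling, 23 with only the compared libraries, 9 with no filter, 2 with the replicate block, 2 with a pseudocount of 0.1, 157 with a minimum fold of 2, 10 with midway tested against each end, and 1 each with array weights, with pairs of times at both ends and without the 2 libraries farthest out. Genes near 1 FPKM have the least depth behind them. Except where stated, the cause of a difference was not tested.

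With an estimated correlation camera called 5 lists at 180 h against 72 h and 13 over the windows and their difference, and fry called 26 at 180 h. A pseudocount of 0.1 left 31 genes from 84 h to 96 h and 0 from 96 h to 108 h (759 at an unadjusted p below 0.05 by limma with a pseudocount of 1), and no filter also left 0 there. With a minimum fold of 2, which by construction keeps fewer genes, counts were 554 and 621 at 180 h, 125 and 47, 24 and 46, and 3 and 2 in the windows, 9, 2, 0 and 1 in the steps from 72, 84, 96 and 108 h, 4 and 0 midway and 46 for the windows' difference. With only the compared libraries, hence fewer samples, 217 rose and 841 fell from 108 h to 144 h, and 32 and 44 from 144 h to 180 h. The 6 steps from 72 h to 144 h then gave 2, 0, 0, 0, 2 and 1, and those from 156 and 168 h 1 and 0. The means of 168 and 180 h against 72 and 84 h gave 2999 genes higher. Tested against each end separately, which by construction keeps fewer genes, 46 were higher and 15 lower midway.

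Replicate numbers do not pair the libraries: of 180 same-number pairs 60 had deviations that correlated over 0.1 (median 0.00959), the 4 pairs of 72 h and 180 h ran from -0.449 to -0.124, and 9 of 40 libraries were on average closest to their own number. The replicate block gave 38 genes from 96 h to 108 h, 2 from 120 h to 132 h and 3 from 132 h to 144 h, and with the block 5 and 13 lists passed at an estimated correlation and 26 by fry. It moved no other count by over 1.5 times.

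Median-ratio scaling gave 601 higher and 759 lower from 108 h to 144 h, 87 and 85 from 144 h to 180 h, 96 genes from 84 h to 96 h, 13 from 96 h to 108 h and 203 higher and 289 lower midway, and 10 lists at 180 h and 24 in the windows with an estimated correlation. Without replicate 4 of 84 h and replicate 1 of 96 h, 1444 genes rose from 72 h to 108 h, 592 from 108 h to 144 h, 103 rose and 185 fell from 144 h to 180 h, 25 changed from 96 h to 108 h, 4 from 108 h to 120 h and 976 between windows. Array weights gave 10587 genes among the times, 3383 higher at 180 h, 3434 and 3358, 1006 and 3107, and 324 and 706 in the windows, 1816, 5598, 479, 158, 78, 365, 40, 343 and 2 in the steps, 1634 and 669 midway and 5758 between windows. Ldha at 180 h turned to -0.0214 under these weights, uncalled either way.

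The control-gene axis as a covariate gave 3140 higher at 180 h, 2262 and 2468, 1494 and 3198, and 343 and 686 in the windows, 1299, 956, 618, 434, 36, 102 and 4 in the steps from 72 h to 156 h, 559 and 272 midway and 1919 between windows. The median of oxidative phosphorylation turned to -0.0366 with it. This covariate, too, comes from these same libraries, so its counts are not independent of their spread. With this covariate 0 and 6 lists passed with an estimated correlation and 27 by fry. The within-time axis as a covariate narrows the spread by construction and gave 9899 genes among the times, 3372 higher at 180 h, 3092 and 2841, 1992 and 3407, and 332 and 1049 in the windows, 2516, 4595, 1246, 1521, 11, 218 and 12 in the steps from 72 h to 156 h, 2226 and 734 midway and 4359 between windows.

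With each library left out in turn, 5769 to 6719 genes differed among times and 1633 to 2048 were higher and 3565 to 4176 lower at 180 h. The windows gave 652 to 1026 and 920 to 1597, 207 to 359 and 804 to 1685, and 39 to 54 and 67 to 115. The lowest counts from 108 h to 144 h came without replicate 4 of 108 h, and without replicates 2 and 3 of 144 h 1034 and 1035 genes fell. Without replicate 1 of 180 h 67 genes fell in the last window. From 72 h to 84 h the range was 53 to 210 (62 and 53 without replicates 3 and 4 of 72 h, 83 and 102 without replicates 2 and 3 of 84 h). From 84 h to 96 h it was 1 to 2218: 368, 1 and 32 without replicates 1, 3 and 4 of 84 h, and 2218, 13, 24 and 17 without replicates 1 to 4 of 96 h. From 96 h to 108 h it was 0 to 35 (35 without replicate 4 of 108 h, 4 without replicate 1 of 96 h, and 0 without replicates 3 or 4 of 96 h or 1 or 2 of 108 h). Later steps gave 0 to 1, except 1 to 2 from 120 h to 132 h. Midway the counts were 133 to 509 (10 of 24 moved by over 1.5 times) and 67 to 341 (11 of 24), and the windows' difference 252 to 493, lowest without replicate 1 of 108 h. The log2 change of Cdkn1a, 180 h against 72 h, ranged from -0.2601, without replicate 1 of 72 h, to 0.2478, uncalled throughout.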

Other observations

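Egr1, an immediate early transcription factor gene, was followed over all times after its step changes had been seen, and Cd53 after the marker test. Egr1 had its highest mean at 120 h, 24.8 ± 9.72 FPKM (n = 4), between 11.4 FPKM at 108 h and 7.60 at 132 h, and its lowest at 180 h, 4.47 FPKM. Cd53, a tetraspanin gene known from blood cells, rose from 0.705 ± 0.193 to 5.69 ± 0.755 FPKM between 72 h and 180 h (log2 change 1.97 ± 0.14, adjusted p = 1.39e-13 by limma), while the means of Csf1r, Cd14, Itgam and Fcer1g were below 1 FPKM at both times.

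Other splits of the same libraries were counted for each comparison, with the real split included. They swapped libraries freely and ignored any matching of cultures across times. A share of 1 of 35 is the smallest possible between 2 times. It was not adjusted over the comparisons, so it argues against chance but does not exclude it. This share was found for 180 h against 72 h (6039 genes, highest other split 3261) and 72 h to 108 h (2293 against 396). It was also found for 108 h to 144 h (1924 against 1) and 144 h to 180 h (170 against 1). For the test over all times the share was 1 of 100 (6118 against 1574). For midway against the pooled ends the share was 3 of 100, and 1 other split reached 3012 genes against the real 426. Those splits mix libraries of different times and can line up with the change over time, so they do not decide on chance. Of the steps, 72 h to 84 h (161 against 18) and 96 h to 108 h (7 against 1) also had a share of 1 of 35. With only the compared libraries the former count was 2 and the latter 0. With 1 library left out the latter was 0 to 35. From 108 h to 120 h (2 against 1) and 120 h to 132 h (1 against 0) the share was also 1 of 35, but it rests on 2 genes and 1, and with any 1 of the 8 libraries left out the former count was 0 or 1. For 84 h to 96 h the share was 7 of 35 (52 against 7268), which points to a structure of the samples. For 168 h to 180 h it was 3 of 35 (1 against 1). Chance cannot be excluded for either step. Where 0 genes passed by limma, the share was 35 of 35, which a count of 0 fixes in advance and which decides nothing. The highest other counts were 1, 0 and 1 for the steps from 132, 144 and 156 h.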
